A study of Danio rerio with 6 samples.

How the data were processed

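Fin folds of 3-day-old zebrafish larvae were sampled uncut or 4 h after amputation, with 3 libraries per group. Per the labels' protocols, folds were taken into cold buffer, total RNA was extracted with Trizol, and libraries were made with a TruSeq RNA kit, which in this form does not mark strand. The sample descriptions name DMSO, a solvent, but no drug treatment is named. TopHat, Cufflinks and DESeq2 are named in the submitters' processing notes without version, role or order. The read counter, its settings, the genome build and the annotation release are not given in the sources used here. Reads of near-identical paralogs, such as globin or myosin heavy chain genes, and of overlapping or antisense genes may therefore be split or shared in an unknown way.

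The deposited table held whole-number counts per Ensembl gene for 6 libraries and 32266 genes. Beside them stood a normalized signal that the authors made by dividing each library's counts by a size factor, tested here on the values (largest relative deviation 5.5e-10), and its mean over the libraries. The authors' log2 fold change, its standard error and their Wald score were given per the file headers, as uncut over amputated, and were turned round here wherever a direction is stated. The authors' p-value and adjusted p-value were deposited beside them, with 12918 genes at NA. All 12 per-sample columns were matched to samples by name. A spreadsheet had turned 20 gene names into dates, of which 19 were restored through the gene ID. Of the table's IDs, 26433 were in the gene name table, which gave symbols to 2864 clone-style names.

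Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and glmQLFit and glmQLFTest compared the groups with no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are amputated over uncut, and their standard error is the absolute log2 fold change over the square root of the test's F. Levels are counts scaled to a common library total after TMM (CPM), given as mean ± SD. A count of 1 was worth 0.0436 to 0.0972 CPM. Where a group had 0 counts, the fold was bounded with a floor of 3 counts over that group's libraries. That floor covers counting error only, since reads carried no molecular identifiers, while the SD and the standard error include the spread between libraries.

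The pipeline was tested on simulated counts for this comparison and 17883 genes, with 200 genes changed. It called 34%, 88%, 98% and 100% of 50 genes each at log2 fold changes of 0.5, 1, 2 and 3, and 8 of 17683 unchanged genes.

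Before the data were examined, 41 gene lists were written from textbook knowledge of wounding, fin regeneration, signalling pathways and cell types. Of 1454 members written by name, 1414 were found (33 of them by ID under another name), and 2 lists were taken by name pattern. Lists were tested with limma 3.58.1, by camera on voom values with a preset inter-gene correlation of 0.01, with fry beside it, and adjusted over the 41 lists. Genes named in the text were chosen by a rule fixed at the same time. It took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM, groups that do not overlap and a given symbol, then up to 4 members of each list by smallest adjusted p (the 2 with the highest mean where none passed), and a fixed set of wound and regeneration genes. Genes named outside it were chosen after their values were seen: fn1a, vcana, col1a1a, agr2, arhgdig, rac2, atp2a1, nfkbiaa, nfkbiab, mpeg1.2, ccnb1, top2a, hsp70.1, hsp70.2, serpinh1a, serpinh1b, and those of the closing section's name families. Also chosen after their values were seen were dusp2, dusp5, fosb, jun and jund. Not every list member that the rule named is reported here. Setting lepb to its bound left the medians of its lists as they were.

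Replicate numbers were checked for pairing. Deviations from the group means correlated across genes at 0.222, 0.199 and 0.153 for same-numbered libraries and at −0.143 to −0.04 for the others. Deviations cancel within a group, so positive values for some pairs force negative ones for others. With 3 libraries per group, too few matchings exist to tell pairing from chance. The numbers were therefore treated as a possible pairing, used as a block in an alternative fit only. This possible pairing comes from the data, since the labels give only the numbers.

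The alternatives were DESeq2's size factors in the same fit, DESeq2 1.42.0, the authors' calls, no filter on low counts, a mean of at least 5 CPM, an adjusted p under 0.01, a log2 fold change of at least 1, the replicate number as a block, an estimated inter-gene correlation, and each library left out in turn. Scaling by library totals alone was added after seeing the data.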

Results

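RNA sequencing measured transcript levels in the fin fold of 3-day-old zebrafish larvae. The fin fold is the thin fold of skin around the larval tail, made of epidermal layers over mesenchymal cells and collagen-rich fibres called actinotrichia. A group of 3 libraries came from uncut folds and another group of 3 from folds 4 h after amputation. Total counts were 17019689, 23019556 and 11216130 in uncut replicates 1, 2 and 3, and 18835395, 18595152 and 21128093 in amputated replicates 1, 2 and 3. The labels do not say whether replicates came from separate sets of larvae, so p-values measure only the spread between these samples, which may be technical. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 4.45 to 15.6), so all 6 libraries were counted as separate samples. The first principal component held 66.8% of the variance and parted the groups. Uncut replicate 1 stood apart from the other libraries on the second component, which held 13.7%.

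The comparison asked which transcripts differ between the fold 4 h after amputation and the uncut fold. Genes such as the gelatinase gene mmp9, the AP-1 gene junba and the cytokine gene il11a rose, as did 35 of 44 leukocyte markers and 46 of 50 ribosome biogenesis genes, while 29 of 45 matrix and actinotrichia genes and 14 of 24 fin mesenchyme markers fell. With an estimated correlation camera called none of these lists, with adjusted p = 0.349 for ribosome biogenesis, matrix and neutrophil genes, 0.284 for macrophage and mesenchyme markers and 0.413 for pan-leukocyte markers. In edgeR's quasi-likelihood test, 3724 of 17883 tested genes were higher after amputation and 3499 were lower, at a Benjamini-Hochberg adjusted p under 0.05. Large changes were mostly rises: 810 higher and 566 lower genes changed by at least 1 on the log2 scale, and 60 higher and 8 lower genes by at least 3. The groups did not overlap in 51.1% of tested genes, where chance gives 10% for 3 against 3. When libraries were scaled by their totals alone, a choice made after seeing the data, 6821 genes were higher and 1636 lower, and the median of all tested genes moved from 0.003 to 0.26 on the log2 scale. Changes below are therefore relative to the bulk of tested genes, as set by TMM scaling. In the authors' deposited table, 3786 genes were called higher after amputation and 3681 lower. Of these calls in the authors' deposited table, 3650 higher and 3443 lower genes were also called here, with 0 opposite calls.

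The 8 largest rises among genes that met the naming rule were in gcga (glucagon), ednrbb (an endothelin receptor), fstl3 (a follistatin-like activin antagonist), the collagenase mmp13a, the gelatinase mmp9, the growth factor fgf20a, lect2l and the AP-1 gene junba. The log2 fold change was 5.88 ± 0.35 (SE) for gcga, 5.59 ± 0.22 for ednrbb, 5.43 ± 0.24 for fstl3 and 4.87 ± 0.24 for mmp13a. For mmp9 it was 4.65 ± 0.16, for fgf20a 4.47 ± 0.16, for lect2l 4.26 ± 0.30 and for junba 4.11 ± 0.11. The level of mmp9 (chromosome 8, 24260273 to 24274708) went from 39.8 ± 2.26 CPM (SD, n = 3) in uncut folds to 994 ± 209.5 CPM (SD, n = 3), with an edgeR adjusted p of 4.5e-09. The gene fgf20a (chromosome 1, 15700140 to 15701877), whose loss blocks fin regeneration, went from 1.17 ± 0.27 to 25.2 ± 0.53 CPM (SD, n = 3), with an edgeR adjusted p of 5.3e-09. Coordinates are those of the deposited table, whose genome build is not given in the sources used here. The leptin gene lepb had 0 counts in all 3 uncut libraries and 3.87 ± 1.35 CPM (SD, n = 3) after amputation, at least 60.5-fold higher against a floor of 3 counts over the uncut group.

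**Figure D1:**
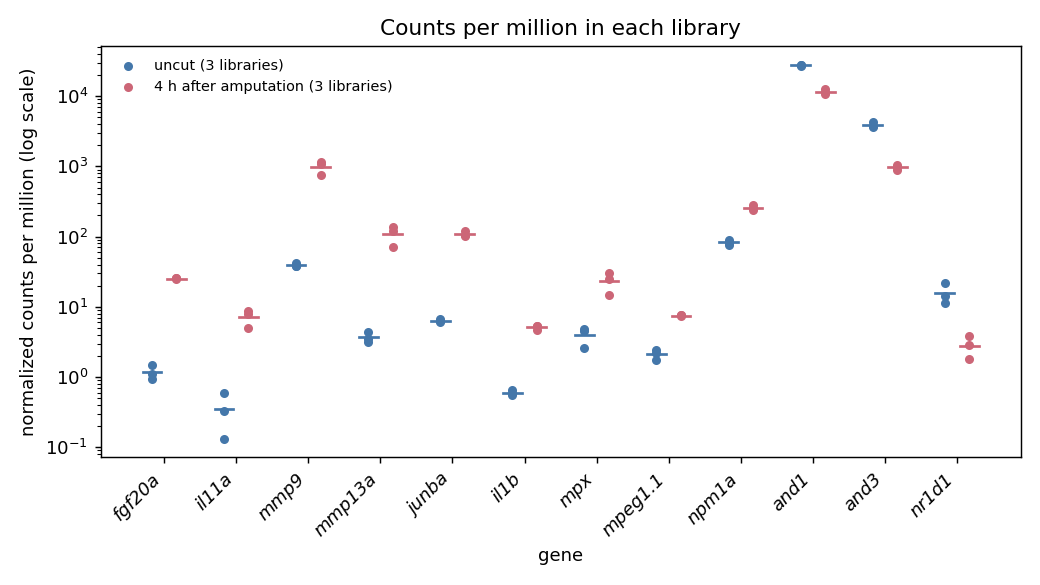
Normalized counts (CPM) on a log axis for 12 genes in each of the 6 libraries, with blue points for uncut folds, red points for folds 4 h after amputation and a bar at each group's mean. The 3 amputated libraries lie above the 3 uncut ones for fgf20a, il11a, mmp9, mmp13a, junba, il1b, mpx, mpeg1.1 and npm1a and below them for and1, and3 and nr1d1.

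Matrix proteases and their inhibitors moved both ways. Of 29 tested, 14 rose and 10 fell (14 and 12 adjusted over the list alone), and camera, which compares a list with other genes, did not call the list (adjusted p = 0.247), while fry's directional test was upward (adjusted p = 0.00379). Besides mmp9 and mmp13a, the metalloproteases adam8a (2.65 ± 0.14) and adam8b (2.60 ± 0.11) rose. In the list of fin fold regeneration genes, 14 of 29 rose and 7 fell (14 and 8 adjusted over the list alone), with camera adjusted p = 0.0316 upward, adjusted p = 0.413 with an estimated correlation and 0.0639 with library totals alone. The fibronectin gene fn1b rose by 3.79 ± 0.10, from 213 ± 6.90 to 2945 ± 273 CPM (SD, n = 3), and aldh1a2, which makes retinoic acid, by 1.69 ± 0.22. The activin subunit gene inhbaa rose by 0.69 ± 0.10. The msh-type homeobox genes msx1b and msx3 went the other way, at −0.68 ± 0.08 and −1.14 ± 0.08. The gene wnt10a was at 0.09 ± 0.10 and did not pass the test, but was at 0.34 with library totals alone (edgeR adjusted p = 0.0196), within the general shift of that scaling. The growth factor gene mdka was at −0.25 ± 0.12 with an edgeR adjusted p of 0.107, which fell to 0.00976 with the replicate number as a block.

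Some immediate early and AP-1 genes rose strongly, while others did not change or fell. In this list 10 of 28 rose and 4 fell (11 and 6 adjusted over the list alone), with camera adjusted p = 0.0161 upward and adjusted p = 0.387 with an estimated correlation. The rises included junbb (2.64 ± 0.09), fosl1a (2.83 ± 0.21) and fosl2 (2.56 ± 0.14), and also dusp2 (2.777) and dusp5 (2.445). In contrast fosab, the classic c-Fos gene, was at −0.18 ± 0.17 and did not pass the test. Nor did fosb, jun and jund, at 0.05, 0.16 and 0.06. In the list of JAK-STAT and IL-6 family genes, 12 of 24 rose and 5 fell (13 and 6 adjusted over the list alone), with camera adjusted p = 0.0356, adjusted p = 0.349 with an estimated correlation and 0.0749 with library totals alone. The cytokine il11a rose by 4.45 ± 0.37, the shared receptor chain il6st by 1.74 ± 0.08, stat3 by 1.17 ± 0.09 and the feedback inhibitor socs3b by 2.44 ± 0.17, while cish, another feedback inhibitor, fell by 1.36 ± 0.09. Of 11 interferon response genes, 2 rose and 2 fell, with the same counts adjusted over the list alone and camera adjusted p = 0.553. They were stat1b and irf9, which were higher, and mxc and irf7, which were lower. The call of irf7 was lost without uncut replicate 1 (edgeR adjusted p = 0.0731), amputated replicate 1 (0.0801) or amputated replicate 2 (0.0573), and with library totals alone (0.09).

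Cytokine and NF-kB target genes were set beside markers of leukocytes. Of 26 cytokines, chemokines and NF-kB targets, 12 rose and 2 fell, with the same counts adjusted over the list alone, camera adjusted p = 0.00261 and adjusted p = 0.349 with an estimated correlation. The interleukin gene il1b rose by 3.08 ± 0.24, from 0.60 ± 0.052 to 5.09 ± 0.38 CPM (SD, n = 3), and nfkb1 by 0.78 ± 0.12, while the NF-kB inhibitor genes nfkbiaa and nfkbiab were the 2 that fell (−0.37 and −0.67). The neutrophil chemokine gene cxcl8a was at 0.32 ± 0.23 and did not pass the test, with 0.61 and an edgeR adjusted p of 0.0371 when uncut replicate 1 was left out. Reads of tnfa were too few to test, with 4 counts over the amputated group and 2 over the uncut group. Of 16 neutrophil markers, 14 rose and none fell, adjusted over all genes and adjusted over the list alone, with camera adjusted p = 1.5e-07 and adjusted p = 0.349 with an estimated correlation. The neutrophil peroxidase gene mpx rose by 2.50 ± 0.26. Of 16 macrophage markers, 13 rose and 1 fell, with the same counts adjusted over the list alone, camera adjusted p = 6.7e-06 and adjusted p = 0.284 with an estimated correlation. The pore-forming protein gene mpeg1.1 rose by 1.80 ± 0.18, the transcription factor gene irf8 by 3.00 ± 0.27, and the cathepsin gene ctss2.1 by 3.41 ± 0.15 (the 1 that fell was mpeg1.2, at −0.61). Of 13 pan-leukocyte markers, 9 rose and 2 fell (10 and 2 adjusted over the list alone), with camera adjusted p = 0.00103 and adjusted p = 0.413 with an estimated correlation. In that list plek rose by 4.04 ± 0.32, lcp1 by 2.93 ± 0.21 and coro1a by 2.40 ± 0.13, and the 2 that fell were arhgdig (−0.63 ± 0.09) and rac2 (−0.32 ± 0.09).

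Most genes that build ribosomes rose. Of 50 genes of ribosome biogenesis and translation, 46 rose and none fell (47 and 0 adjusted over the list alone), with camera adjusted p = 4.3e-24 and adjusted p = 0.349 with an estimated correlation. Their median log2 fold change was 0.96. The nucleolar chaperone gene npm1a rose by 1.64 ± 0.09, mybbp1a by 1.28 ± 0.09, nol6 by 1.23 ± 0.09 and rrp12 by 1.16 ± 0.08. Genes caught by name as cytosolic ribosomal proteins did not follow, with 2 of 89 higher and 2 lower (1 and 0 adjusted over the list alone), camera adjusted p = 0.023 downward and adjusted p = 0.747 with an estimated correlation. The members that passed were rpl7l1, a ribosomal protein-like gene, and rps6ka1, rps6ka5 and rps6kal, which encode ribosomal S6 kinases and not ribosomal proteins. The call of rps6ka1 was lost without uncut replicate 2 (edgeR adjusted p = 0.0927), uncut replicate 3 (0.0758), amputated replicate 1 (0.107) or amputated replicate 3 (0.0664), and that of rps6kal was kept only without uncut replicate 1 among fits with a library left out. The list of cytosolic ribosomal protein genes had a median of −0.12 that was above 0, at 0.14, with library totals alone. Its call was lost without uncut replicate 1 (camera adjusted p = 0.933), amputated replicate 2 (0.177) or amputated replicate 3 (0.0581).

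Cell cycle genes rose in part. Of 55 tested, 23 rose and none fell, with the same counts adjusted over the list alone, camera adjusted p = 0.00034 and adjusted p = 0.522 with an estimated correlation. The replicative helicase genes mcm4, mcm5 and mcm6 rose by 1.18 ± 0.09, 1.12 ± 0.08 and 1.11 ± 0.07, and uhrf1 by 1.21 ± 0.09. The mitotic genes ccnb1 and top2a were at −0.06 and −0.07 and did not pass the test. Of 45 heat shock and unfolded protein genes, 19 rose and 2 fell, with the same counts adjusted over the list alone, camera adjusted p = 0.00579 and adjusted p = 0.522 with an estimated correlation. The chaperone gene hspa4a rose by 1.45 ± 0.11, and the mitochondrial chaperone genes hspd1, hspe1 and hspa9 by 1.22 ± 0.09, 0.99 ± 0.09 and 0.76 ± 0.09. The inducible genes hsp70.1 and hsp70.2 rose by 2.81 ± 0.62 and 2.88 ± 0.61. The 2 that fell, serpinh1a and serpinh1b (−0.35 and −1.10), encode the collagen chaperone. Of 57 mitochondrial respiratory chain genes, 12 rose and 2 fell (9 and 1 adjusted over the list alone), with camera adjusted p = 0.0272 upward and adjusted p = 0.702 with an estimated correlation. That call was lost without uncut replicate 3 (camera adjusted p = 0.168), without amputated replicate 1 (0.0683) and without amputated replicate 3 (0.0581). Of 13 mitochondrially encoded genes, 3 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.131). That list of mitochondrially encoded genes passed without uncut replicate 1 (camera adjusted p = 0.00251), with no filter on low counts (0.0448) and with library totals alone (0.0205).

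Many structural genes of the fold fell. Of 45 extracellular matrix and actinotrichia genes, 29 fell and 3 rose, with the same counts adjusted over the list alone, camera adjusted p = 2.3e-07 and adjusted p = 0.349 with an estimated correlation. The actinotrichia protein genes and1, and2 and and3 fell by 1.25 ± 0.12, 1.16 ± 0.12 and 2.01 ± 0.10. The level of and1 (chromosome 24, 26134462 to 26138318) went from 27714 ± 445 to 11686 ± 1034 CPM (SD, n = 3). Together and1, and2 and col1a1a took 12.8%, 14.1% and 14.2% of the counts in uncut replicates 1, 2 and 3, and 7.35%, 7.30% and 8.12% in amputated replicates 1, 2 and 3. The 3 matrix genes that rose were fn1b, fn1a and vcana, which encode fibronectins and a versican. Of 24 fin mesenchyme and osteoblast markers, 14 fell and none rose (14 and 1 adjusted over the list alone), with camera adjusted p = 0.00013 and adjusted p = 0.284 with an estimated correlation. In that list twist3 fell by 0.80 ± 0.08.

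**Figure D2:**
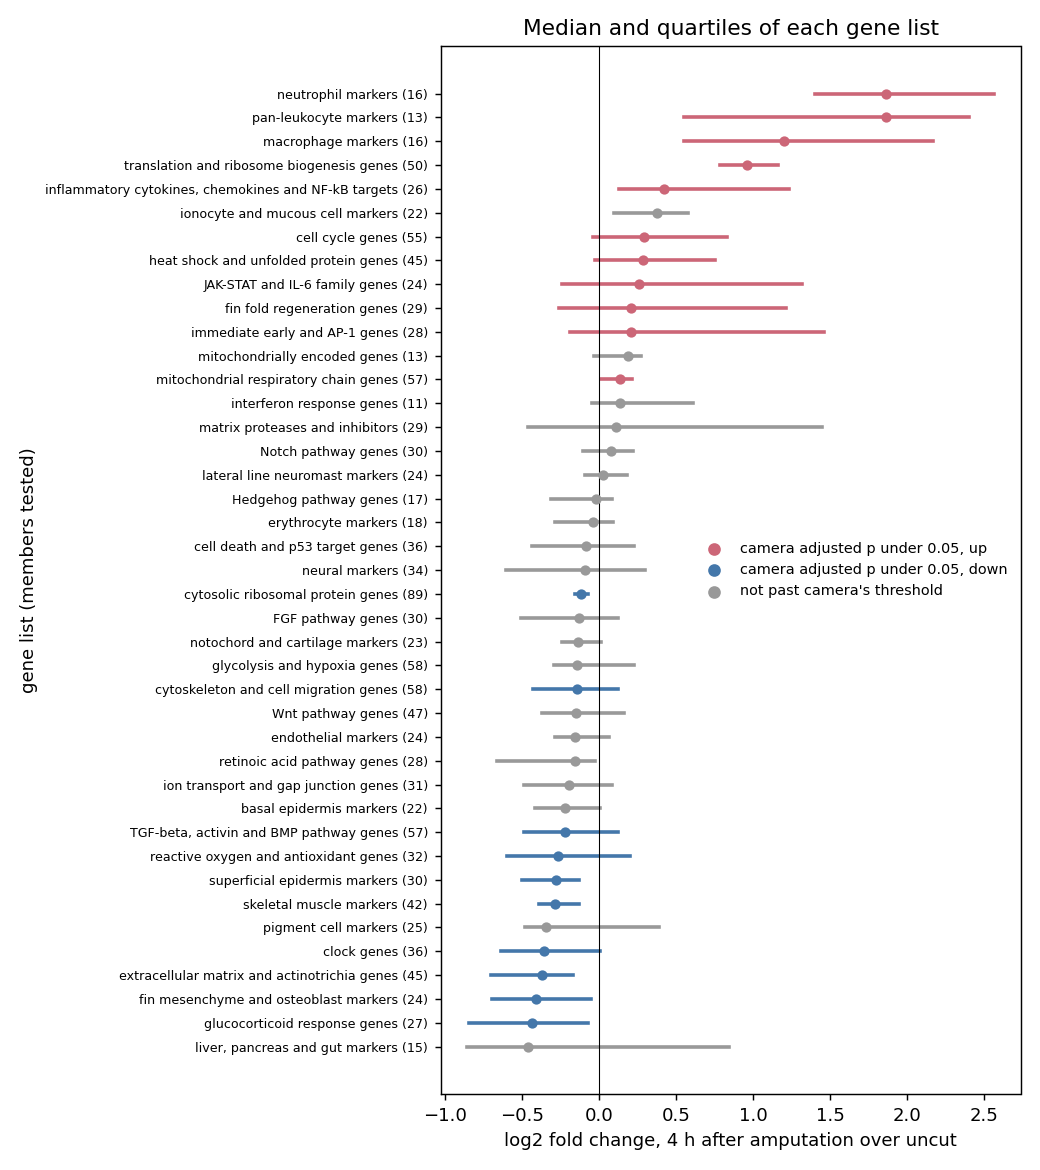
Median log2 fold change, amputated over uncut, of each of the 41 gene lists (points) with the lower and upper quartiles of its members (lines), coloured by camera's call with the preset correlation. The neutrophil, pan-leukocyte and macrophage lists have the highest medians at 1.87, 1.86 and 1.2, followed by ribosome biogenesis at 0.96. With library totals alone every median moves up, and those of the Wnt, FGF and TGF-beta lists, among others, are then above 0.

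Many markers of the superficial epidermis fell, with a median of −0.28 that was −0.02 with library totals alone. Those of the basal layer had a median of −0.22 that was above 0, at 0.04, with library totals alone. Of 30 superficial epidermis markers, 17 fell and 1, agr2, rose, with the same counts adjusted over the list alone, camera adjusted p = 0.00077 and adjusted p = 0.387 with an estimated correlation. The annexin genes anxa1a and anxa1c fell by 0.77 ± 0.08 and 0.83 ± 0.11. Of 22 basal epidermis markers, 11 fell and 2 rose, with the same counts adjusted over the list alone. For these basal epidermis markers the camera adjusted p was 0.0616, but 0.0444 with the replicate number as a block, 0.0365 without uncut replicate 2 and 0.0349 without amputated replicate 1. The keratinocyte transcription factor gene tp63 fell by 0.50 ± 0.08, and cldn1 by 0.88 ± 0.11. Among those that rose was the basement membrane gene lamb3, at 6.45 ± 0.47, with 0, 3 and 1 counts in uncut replicates 1, 2 and 3 and 162, 116 and 238 in amputated replicates 1, 2 and 3. Of 22 ionocyte and mucous cell markers, 8 rose and 2 fell, with the same counts adjusted over the list alone and camera adjusted p = 0.0743. The ionocyte and mucous cell markers passed with the replicate number as a block (camera adjusted p = 0.029), with no filter on low counts (0.037) and without amputated replicate 3 (0.0208). The mucin genes muc5.1 and muc5.2 rose by 0.81 ± 0.11 and 0.71 ± 0.09, while the ammonium transporter gene rhcga fell by 1.59 ± 0.17.

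Of 58 cytoskeleton and cell migration genes, 25 fell and 11 rose (26 and 11 adjusted over the list alone), with camera adjusted p = 0.045 downward and adjusted p = 0.522 with an estimated correlation. That call was lost without amputated replicate 3 (camera adjusted p = 0.108), amputated replicate 2 (0.0655), uncut replicate 1 (0.0583) or uncut replicate 2 (0.0519), and with library totals alone (0.244), where the list's median was 0.11 and not −0.14. The fibronectin receptor gene itga5 rose by 1.66 ± 0.10 and itgb6 by 0.98 ± 0.09, while krt8 fell by 0.90 ± 0.09. Of 31 ion transport and gap junction genes, 10 fell and 4 rose, with the same counts adjusted over the list alone and camera adjusted p = 0.122. The heat-gated channel gene trpv1 rose by 2.85 ± 0.26 and trpm4a fell by 1.3 ± 0.09.

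Most developmental pathway lists held both rises and falls, in a comparison where 40.4% of all tested genes were called. A share near or below that in a list does not mark the list out. Of 57 TGF-beta, activin and BMP pathway genes, 22 fell and 10 rose (25 and 10 adjusted over the list alone), with camera adjusted p = 0.0247 downward, adjusted p = 0.349 with an estimated correlation, and a median of −0.22 that was above 0, at 0.03, with library totals alone. The BMP target gene id1 fell by 0.78 ± 0.09 and bmp1a by 0.90 ± 0.09, while fstb, a follistatin gene, rose by 2.75 ± 0.14. Of 47 Wnt pathway genes, 17 fell and 8 rose (17 and 9 adjusted over the list alone; camera adjusted p = 0.247). The Wnt antagonist gene dkk1b fell by 2.31 ± 0.15 and tcf7l2 by 0.85 ± 0.09, while wnt5a rose by 0.77 ± 0.09. Of 30 FGF pathway genes, 12 fell and 4 rose, with the same counts adjusted over the list alone and camera adjusted p = 0.114. Beside the rise of fgf20a, fgfbp2a fell by 2.22 ± 0.20, fgfr4 by 0.85 ± 0.08 and the feedback inhibitor gene spry2 by 0.75 ± 0.08. Of 28 retinoic acid pathway genes, 9 fell and 2 rose, with the same counts adjusted over the list alone and camera adjusted p = 0.0743. Of 17 Hedgehog pathway genes, 5 fell and none rose, with the same counts adjusted over the list alone and camera adjusted p = 0.36. Of 30 Notch pathway genes, 4 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.595).

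Metabolic and stress lists were also mixed, to be read against the same 40.4% of all tested genes called. Of 58 glycolysis and hypoxia genes, 14 rose and 12 fell (14 and 13 adjusted over the list alone; camera adjusted p = 0.569), and igfbp1a rose by 2.55 ± 0.21 while pfklb fell by 1.03 ± 0.12. Of 36 cell death and p53 target genes, 12 fell and 7 rose (14 and 8 adjusted over the list alone; camera adjusted p = 0.36). Of 32 reactive oxygen and antioxidant genes, 16 fell and 7 rose (17 and 7 adjusted over the list alone), with camera adjusted p = 0.0331 downward and adjusted p = 0.522 with an estimated correlation. That call was lost without uncut replicate 1 (camera adjusted p = 0.0615) and without amputated replicate 3 (0.0782). In that list gstp1 fell by 1.22 ± 0.10, and the haem oxygenase gene hmox1a rose by 1.60 ± 0.19.

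Many genes of the circadian clock and of the glucocorticoid response fell. Of 36 clock genes, 16 fell and 2 rose (17 and 2 adjusted over the list alone), with camera adjusted p = 0.015 and adjusted p = 0.536 with an estimated correlation. The camera adjusted p was 0.0691 without amputated replicate 3. The clock repressor genes nr1d1 and per1a fell by 2.46 ± 0.27 and 1.74 ± 0.26. The time of day of collection is not given in the sources used here. Of 27 glucocorticoid response genes, 13 fell and 4 rose (14 and 4 adjusted over the list alone), with camera adjusted p = 0.0132 and adjusted p = 0.349 with an estimated correlation. In it tsc22d3 fell by 0.93 ± 0.12 and zbtb16b by 1.26 ± 0.16. The 8 largest falls among genes that met the naming rule included nr1d1, dkk1b and fgfbp2a. The others were mslna (−4.33 ± 0.25), nrip2 (−2.46 ± 0.14), hecw2a (−2.25 ± 0.16), ethe1 (−2.15 ± 0.21) and pdzrn3a (−2.14 ± 0.19). The mesothelin-type gene mslna (chromosome 3, 43134641 to 43171972) went from 130.1 ± 31.1 to 6.43 ± 2.75 CPM (SD, n = 3), with an edgeR adjusted p of 4e-07.

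Markers of other tissues that a fold sample can carry were tested in the same way, to be read against the same 40.4% of all tested genes called. Of 42 skeletal muscle markers, 15 fell and none rose, adjusted over all genes and adjusted over the list alone. Their median was −0.29, and −0.029 with library totals alone. For these muscle markers the camera adjusted p was 0.00106, and 0.533 with an estimated correlation. Of 34 neural markers, 7 fell and 2 rose, with the same counts adjusted over the list alone and camera adjusted p = 0.438. Of 23 notochord and cartilage markers, 4 fell and 3 rose (3 and 2 adjusted over the list alone; camera adjusted p = 0.219). Of 24 endothelial markers, 3 fell and none rose, with the same counts adjusted over the list alone and camera adjusted p = 0.141. Of 25 pigment cell markers, 9 fell and 5 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.303), among which kita fell by 1.03 ± 0.13. Among 24 lateral line neuromast markers 1 fell (0 adjusted over the list alone; camera adjusted p = 0.989). Among 18 erythrocyte markers 3 fell and 1 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.569). Among 15 liver, pancreas and gut markers 4 rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.438).

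Of the 41 lists, camera called 11 upward and 10 downward with its preset correlation, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fry's mixed test, which asks whether members change in either direction, passed for 38 lists at an adjusted p under 0.05. Among lists that camera called, fry's directional test did not pass for muscle (adjusted p = 0.0698), clock (0.113), respiratory chain (0.182) and ribosomal protein genes (0.48). Besides the proteases, it passed for lists that camera did not call. They were the retinoic acid (5.3e-04), ion transport (0.00306), liver, pancreas and gut (0.013), FGF (0.0159), Wnt (0.0176), ionocyte (0.0367) and basal epidermis (0.044) lists.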

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

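Scaling by library totals alone was the only setting chosen after seeing the data. The counts of 3724 higher and 3499 lower genes stayed within 1.5 times under DESeq2's size factors, DESeq2, the authors' calls, both filters and the replicate block, which gave 4125 and 4016. With a library left out they ranged from 3011 to 3869 higher and 2732 to 3667 lower, and 4920 of the 7223 calls were kept in every such fit. Stricter thresholds lowered the counts by construction, to 2283 lower genes at an adjusted p under 0.01, and to 810 higher and 566 lower at a log2 fold change of at least 1. Library totals alone gave 6821 higher and 1636 lower. Under them rps6kal was at 0.014 and the ribosomal protein list had turned upward (camera adjusted p = 0.507), both against calls downward, within that scaling's shift of all genes by 0.26; for the list the cause was not tested. Camera called 21 lists, 0 with an estimated correlation, and 17 to 21 with a library left out, newly called lists included. The replicate block changed the calls of mdka and of the basal epidermis and ionocyte lists, and no other call of a named gene or list. Of 162 called named genes, 143 kept their call under every alternative except the stricter thresholds. Depth limits low genes such as tnfa. Changes of 0.5 on the log2 scale were mostly missed in simulation, where only 200 of 17883 genes were changed. In the data 40.4% of tested genes were called, which makes the adjusted threshold easier to pass, so the simulated share missed does not carry over.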

Other observations

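All tests in this part were chosen after the results were seen, except the splits of the libraries for genes and the tests of depth, of clock time and of trunk tissue for all changed genes. Gene families that share a name stem, with at least 10 tested members, were tested as well. Members of the 41 lists were not taken out, so some stems recount genes of those lists. Among them are klf2a, klf4 and klf6a of the immediate early list, and adamts1, adamts9 and adamts15a of the protease list. Of 183 such stems, camera called 24 upward and 9 downward, and 0 with an estimated correlation, where 12 had an unadjusted p under 0.05. Genes of the mitochondrial ribosome rose together, with 40 of 45 mrpl genes and 26 of 28 mrps genes higher and none lower (camera adjusted p = 1.7e-11 and 4.6e-08, and adjusted p = 0.517 for both with an estimated correlation). The subunit gene mrpl46 rose by 1.11 ± 0.15 (SE). Of 20 nup genes, which encode nuclear pore proteins, 18 rose and none fell (camera adjusted p = 1.4e-09, and adjusted p = 0.351 with an estimated correlation), with nup50 at 1.07. Of 15 psmd genes, which encode proteasome subunits, 14 rose and none fell (camera adjusted p = 5.5e-07, and adjusted p = 0.517 with an estimated correlation). Subunits of RNA polymerases (polr, 25 of 28) and DEAD-box RNA helicases (ddx, 25 of 32) also rose with none lower (camera adjusted p = 1.0e-09 and 7.2e-10, and adjusted p = 0.517 for both with an estimated correlation).

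Among transcription factors, 11 of 19 klf genes fell and 1, klf12a, rose (camera adjusted p = 0.0106, and adjusted p = 0.517 with an estimated correlation), with klf3 at −1.24, klf9 at −1.22 and klf11a at −1.16. Of 14 adamts genes, which encode secreted proteases, 8 fell and adamts15a rose by 1.98 (camera adjusted p = 0.0267, and adjusted p = 0.638 with an estimated correlation). The medians of all these stems kept their sign under both other scalings.

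The groups differed in 7223 genes, and a first pattern to weigh is this difference as a whole. Only 1 of the 10 splits of the 6 libraries, the real one, called as many genes. The highest of the other splits called 0 by edgeR, with 77 to 534 genes at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 same-numbered pairs also called 0. Each of the other splits puts libraries of both groups on both sides, so the group difference widens the spread within a side. That lowers their calls, and the splits cannot decide whether the grouping arose by chance. Depth is argued against, since totals overlapped and thinning to 11216130 counts left 91.5% of the number of calls. Muscle carried in the clips is argued against for genes changed at least 2-fold, because the muscle median was −0.287 with no member at −1 or lower (atp2a1 went from 992.5 to 754 CPM). That test looked at muscle alone, so it does not cover other trunk tissue. For other trunk tissue, and for smaller changes, a difference in tissue cannot be told apart. The notochord median of −0.134 and the neural median of −0.088 lay on the same side as muscle. Both were above 0 with library totals alone, where the muscle median was −0.029.

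A difference in the clock time of collection stays open for all changed genes, as collection times are not given in the sources used here. Of the clock list, 50% passed the threshold, beside 40.4% of all tested genes. Fry's mixed test passed for it (adjusted p = 0.0012), as for 38 of the 41 lists. These values cannot decide the question, and amputation itself may also change clock genes. For gene lists, 1 of the 10 splits called as many as the real split's 21, the highest of the others called 16 and the lowest 6. With 10 splits the share cannot be under 0.05, and the other splits mix both groups on each side here too. No conclusion about chance is drawn from them.

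Leukocyte markers were higher after amputation, by medians of 1.87 for neutrophil and 1.2 for macrophage markers. A smaller share of the other cells of the clip would raise all remaining types alike, which is argued against because the highest median among endothelial, erythrocyte, neural, pigment, neuromast and muscle lists was 0.028. A candidate explanation is more leukocytes in the amputated clips, as 79.5% of 44 distinct leukocyte markers were higher and 3 were lower. Of these markers, 33 were at 1 CPM or more in uncut folds, 6 are in other lists, and the most abundant ones, arhgdig (250.6 to 162 CPM) and rac2 (134 to 107 CPM), fell. Induction in cells already present was not tested and stays open.

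Actinotrichia genes were lower after amputation. Loss of fin mesenchyme cells as a whole is argued against as the only source of the fall. The other 22 mesenchyme markers had a median of −0.371 (quartiles −0.56 and −0.02), above the −1.25, −1.16 and −2.01 of and1, and2 and and3. Of these 22, 12 were lower and none higher, which leaves room for a partial loss. Whether the markers are shared with other cells was not tested. The scaling of the libraries is argued against too, since and1, and2, and3 and col1a1a were at −0.788 or lower under every alternative fit. Of these fits, only DESeq2's size factors, DESeq2, the authors' values and library totals alone changed the scaling. Lower expression in remaining cells and loss of a subset of them near the wound, by the amputation itself, both stay open and were not tested.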
